A study of Mus musculus with 6 samples.

How the data were processed

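The samples were 6 RNA preparations of LβT2 cells, 1 for each of activin A and vehicle at 1, 2 and 6 h, each hybridised to 1 mouse genome array. Groups and times were taken from the labels. The labels describe 1 culture per combination and give no replicates, so a single time has no test.

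The main values are intensity values, the linear signal of each probe set, which the authors deposited after processing with GCOS 1.4, per the submitters' processing notes. The settings of that program, detection calls and the software's scaling options are not given in the sources used here; from the values, each array had been scaled to a mean of 500 after its lowest and highest 2% of values were set aside. The authors also deposited tables of signed fold changes, a score in which a fall is negative; per the file headers they list part of the genes past a fold threshold and a signal difference of 100, and the program that made them is not given in the sources used here. No raw scans were used here, so background correction and probe summary could not be varied.

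Of 45101 probe sets, 64 control probe sets were set aside. The platform annotation named 1 gene for 34945 of the rest, several genes for 932 and none for 9160; only the first kind was named. Symbols were updated through Entrez identifiers to the RefSeq table of assembly GRCm38.p6 for 34741 probe sets and kept as listed for 204. No coordinates were used. Signals were converted to log2 with a pseudocount of 0. A probe set was kept when its mean log2 over the 6 arrays exceeded the median of all probe sets (7.28, a signal of 155.2), which left 22518 probe sets, 19608 of them with 1 gene. Each gene was represented by its brightest probe set, which gave 11408 genes, 4990 of them with more than 1 probe set past the filter.

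The time-averaged effect of activin was tested with limma 3.58.1 in R 4.3.3, by an additive model with time as a block and treatment as the tested term, 2 residual and 3.06 prior degrees of freedom, two-sided, with Benjamini-Hochberg adjustment at 0.05. Its error is how far the 3 log2 ratios differ, drawn by the prior toward the spread of all genes, so a gene that responds at 1 time is not favoured. The SE values given after ± use this moderated variance and can be smaller or larger than the 3 ratios of a gene alone would give. Because nothing in the labels describes repeated cultures of a time, these p-values rest only on the spread between the 3 pairs of arrays, in the gene itself and, through the prior, in all genes. Times were compared in the same fit. At single times, genes at least 1.5-fold apart were counted and set beside the counts between vehicle arrays. Genes at least 1.2-fold apart the same way at all 3 times were set beside the counts with the arrays of 1 time exchanged. Gene lists, 25 in number with 404 of their 594 entries measured, were tested with limma's camera at a preset correlation of 0.01 and described at each time by the percentile of their median among 10000 random lists of matched mean expression. Members were adjusted over all genes and over the list alone.

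The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took the largest changes past the test (none), at each time the 6 highest and 6 lowest ratios, as deposited, outside the range of the 3 vehicle arrays with clone names passed over, 16 fixed genes of activin and gonadotrope biology (1 of them is not reported here), and the members of each described list with the largest mean ratios. Folds of these ratios were printed with signals under 155.2 raised to that value, a form chosen after the values were seen. Genes steady over the 3 times and genes led by time were added after the values were seen, as the text says. Alternatives were no filter, a filter at the 70th percentile, quantile normalization, median centring, a pseudocount of 48, the median of a gene's probe sets, no block, limma-trend with a robust prior, leaving out each time, a 2-fold threshold, other references among the vehicle arrays, camera with an estimated correlation, and fry, by its directional and its mixed test. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

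The test was tried on simulated data for the same 11408 genes, with 50 genes changed at each of 4 sizes in each of 20 sets. The time-averaged test recovered 13.2% of genes changed 1.5-fold, 78.5% at 2-fold, 93.6% at 3-fold and 96.9% at 4-fold, when the change was equal at all times. The sets had a mean of 148 calls each, and the Benjamini-Hochberg threshold is more lenient where many genes pass. These shares therefore do not give the recovery where few genes change strongly. A lack of calls in the real data does not exclude steady changes of 2-fold or more. Of unchanged genes, 5% had an unadjusted p under 0.05, and a list of 20 genes shifted by 0.3 on the log2 scale had an unadjusted camera p under 0.05 in 20 of 20 sets. This is an easier mark than the calls on the real lists, which are adjusted over 25 lists. Errors were drawn independently for each gene, so the simulated lists held no correlation between genes and do not show the power for correlated lists.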

Results

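Genome-wide expression was measured in LβT2 cells, a mouse pituitary cell line of gonadotrope type, after treatment with activin A or with vehicle. Activin is a TGF-beta family protein that stimulates the synthesis of follicle-stimulating hormone in gonadotropes. The cells were held for 16 h in medium without serum, then given activin at 30 ng/ml or buffer, and harvested at 1, 2 or 6 h. Each of the 6 combinations was measured on 1 Affymetrix array with 45101 probe sets, so no difference at a single time has a replicate check, and the number of arrays limits the precision of every value. The deposited signals had the same trimmed mean on every array, between 500 and 500.4, and medians between 151 and 166.4. After removal of dim probe sets, 11408 genes were compared. Several genes typical of gonadotropes were bright on the vehicle arrays: the common alpha subunit Cga read 11888.7, 13900.2 and 13746 at 1, 2 and 6 h, and the nuclear receptor Nr5a1 read 3586.9, 3428.9 and 3281.8. Of 25 listed gonadotrope genes 18 were measured past the filter, while Fshb, Otx1, Esr1, Esr2 and Dmp1 were among those that were not. Of the markers of other pituitary cells, prolactin, growth hormone and Sox2 stayed below the filter, while Drd2 (889.2, 961 and 796.7), Tshb (437.4, 451.6 and 450.9), Crhr1, Pomc and Hesx1 passed it. A control stood apart: the probe set for the 5′ region of 18S ribosomal RNA read 12202 on the activin 1 h array, 610 on the vehicle 1 h array and at most 1171 on the others.

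The main question was which genes respond to activin in gonadotrope-like cells. Averaged over the 3 times, genes known to be induced by activin and TGF-beta were higher with activin as a list by limma's camera test with a preset correlation (adjusted p = 0.0262 over the 25 lists), a call that was lost with an estimated correlation (adjusted p = 0.753). The correlation estimated for this list, −0.005, was below the preset 0.01, so a larger estimate was not what lost the call in that setting. An estimate from 2 residual degrees of freedom cannot exclude correlation between its genes. The directional test of fry did not call the list either (adjusted p = 0.258). With an estimated correlation camera has only the 2 residual degrees of freedom of the fit, which leaves it little power over 25 lists. The mean log2 ratio of activin over vehicle was 1.06 ± 0.17 (moderated SE of the additive fit) for the SPRY-domain gene Spsb1, 1.04 ± 0.26 for the Smad co-repressor Skil, 0.92 ± 0.15 for Inhbb, which encodes the activin beta-B subunit, 0.91 ± 0.10 for the cell cycle inhibitor Cdkn2b and 0.85 ± 0.22 for the inhibitory Smad gene Smad7. These means correspond to folds of 2.08, 2.06, 1.89, 1.88 and 1.8. Of the 16 measured members, none passed the limma test adjusted over all 11408 genes. Adjusted over the list alone, 6 were higher (these 5 and Klf10), 1 was lower and 9 did not pass; the lower one was Ski, a relative of Skil, at −0.37 ± 0.09. Over the 12 alternatives the adjusted p of the list lay between 0.00116 and 0.753; it was 0.0646 without the 1 h arrays, 0.107 without the 2 h arrays and 0.00291 without the 6 h arrays. Its median log2 ratio lay at percentile 99.1, 99.7 and 98.6 of 10000 random lists of matched expression at 1, 2 and 6 h. The 1 h ratios use the array with the bright 18S control.

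The members differed in time course. Skil was 3.17-fold higher at 1 h, 2.19-fold at 2 h and 1.25-fold at 6 h, and Smad7 was 2.34-fold, 2.2-fold and 1.14-fold higher. A second, dimmer Smad7 probe set read 885.2 with activin and 87.8 with vehicle at 1 h, 178.2 and 139 at 2 h, and 309 and 106.5 at 6 h, with every vehicle signal under the filter value of 155.2, and the 2 probe sets disagreed on the size at all 3 times. Inhbb was 1.46-fold higher at 1 h, 2.33-fold at 2 h and 1.97-fold at 6 h, and its other probe set gave 1.63-fold, 2.47-fold and 2.09-fold. Cdkn2b was 1.75-fold, 1.75-fold and 2.17-fold higher. These time courses were not tested, since each time has 1 array per treatment.

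**Figure D1:**
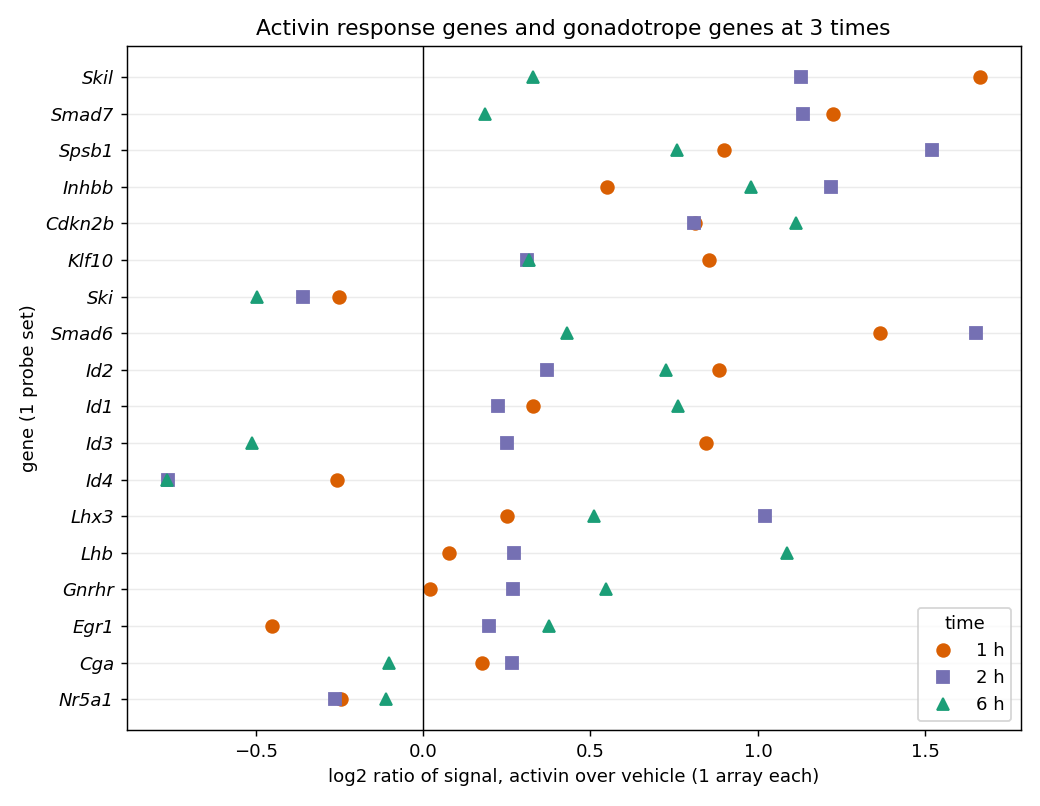
The horizontal axis gives the log2 ratio of signal, activin over vehicle, from 1 array of each, and each row is a gene; circles, squares and triangles stand for 1, 2 and 6 h. Skil and Smad7 had their highest ratios at 1 h (1.66 and 1.22), Inhbb and Spsb1 at 2 h (1.22 and 1.52), and Lhb at 6 h (1.09).

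BMP-responsive genes moved in both directions. The inhibitory Smad gene Smad6 had a mean log2 ratio of 1.15 ± 0.25, the helix-loop-helix inhibitors Id2 and Id1 had 0.66 ± 0.13 and 0.44 ± 0.13, and their relative Id4 had −0.59 ± 0.13. Of the 6 measured members, 3 were higher, 1 was lower and 2 did not pass when adjusted over the list alone; none passed over all genes. Id3 went from 0.84 at 1 h to −0.51 at 6 h, and its mean of 0.20 ± 0.26 did not pass; 1 signal at each time was under the filter value. The list was called higher by camera (adjusted p = 0.0181), and not with an estimated correlation of −0.122 (adjusted p = 0.753), a setting with 2 residual degrees of freedom. The range over alternatives was 0.00237 to 0.753, with 0.0982 without the 1 h arrays and 0.0637 without the 2 h arrays. Its median was at percentile 100, 99.7 and 99.8 at the 3 times. Bambi, a decoy receptor gene, was below the filter.

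Gonadotrope genes were called higher as a list by camera (adjusted p = 0.0262), but not with an estimated correlation of −0.022 (adjusted p = 0.753) and not after quantile normalization (adjusted p = 0.157). Their median log2 ratio was 0.07, 0.19 and 0.04 at 1, 2 and 6 h. Lhb, which encodes the beta subunit of luteinizing hormone, had log2 ratios of 0.08, 0.27 and 1.09 at 1, 2 and 6 h (mean 0.48 ± 0.21), and its signal at 6 h was 1419.7 with activin and 668.3 with vehicle. Gnrhr, the gene of the gonadotropin-releasing hormone receptor, had 0.02, 0.27 and 0.55 (mean 0.28 ± 0.13). A second, dimmer Gnrhr probe set had −0.32 at 1 h, another sign, and 0.04 at 2 h, and at 6 h it read 277.9 with activin and 94.4 with vehicle, the latter under the filter value. The LIM homeodomain gene Lhx3 had 0.25, 1.02 and 0.51, and the PACAP receptor gene Adcyap1r1 had 0.39, 0.23 and 0.52. Nr0b1, a co-repressor of Nr5a1, had a mean of −0.32 ± 0.09, Nr5a1 itself −0.21 ± 0.09, and Cga 0.11 ± 0.11. Egr1 had −0.45 at 1 h and 0.38 at 6 h (mean 0.04 ± 0.18). None of the 18 measured members passed over all genes or adjusted over the list alone. The range of the list's adjusted p over alternatives was 0.0185 to 0.753, with 0.0646 without the 1 h arrays and 0.203 without the 2 h arrays. Fshb, the beta subunit gene of follicle-stimulating hormone, was too dim to be tested: it read 9.7 with activin and 11.1 with vehicle at 1 h, 15.7 and 6.4 at 2 h, and 78.4 and 38.7 at 6 h, all under the filter value of 155.2. Follistatin (Fst) and Inhba were also below the filter.

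Genes of growth factor and early responses split into higher and lower members. Myc, a growth regulator, had a mean log2 ratio of −0.89 ± 0.10, the zinc finger gene Klf6 −0.79 ± 0.15, Ier3 −0.57 ± 0.08 and the MAP kinase phosphatase gene Dusp1 −0.52 ± 0.12. Fos had 0.63 ± 0.16, Nr4a2 0.58 ± 0.16, Dusp2 0.56 ± 0.16 and Jund 0.38 ± 0.08. Some of these values rest on signals under the filter value of 155.2, so their sizes are not well measured: Ier3 read 89.1 with activin and 139.2 with vehicle at 1 h and 134.6 with activin at 2 h, Klf6 135.3 with activin at 1 h and Nr4a2 153.7 with vehicle at 2 h. Adjusted over the list alone, 4 of the 19 measured immediate early genes were higher, 4 were lower and 11 did not pass; over all genes none passed. The camera test did not set the list apart (adjusted p = 0.835), and its median log2 ratio was −0.23, −0.24 and 0.06 at 1, 2 and 6 h. In the list of 10 MAPK feedback genes, Ier3 and Dusp1 were lower adjusted over the list alone and the other 8 did not pass (adjusted p = 0.871 by camera).

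Among the Notch pathway genes, Hes1, a Notch target that represses neurogenic genes, had a mean log2 ratio of 0.74 ± 0.14, and Neurod1, a neurogenic transcription factor gene, had −0.57 ± 0.09; these 2 of the 15 measured Notch genes passed adjusted over the list alone. Neurod4 had a mean of −0.58 ± 0.20, with activin signals under the filter value at 1 h and 2 h, and did not pass. Among 15 Wnt pathway genes, Myc was the single member past the test adjusted over the list alone; Wnt5a had 0.56 ± 0.14 and Axin2, a feedback inhibitor of the pathway, −0.46 ± 0.12, neither past it, and the vehicle signals of Wnt5a were under the filter value at 1 h and 2 h. Bid, a pro-apoptotic gene, had −0.77 ± 0.13 and was the 1 member past that test among 19 apoptosis regulators, but its activin signals were under the filter value of 155.2 at all 3 times, so the size is not measured. Msmo1, an enzyme gene of cholesterol synthesis, had 0.50 ± 0.09 and was the 1 member past it among 16. Cdkn2b was the 1 member past it among 13 G1 cyclins and inhibitors. None of these members passed over all genes, and camera called none of these lists (adjusted p between 0.421 and 0.871).

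The 24 mitosis genes had a median log2 ratio of −0.02 at 1 h, −0.07 at 2 h and −0.14 at 6 h, at percentile 22.2, 0.01 and 0.05 of random lists. The difference between times was not tested for the list, and members varied, with Aurka at −0.22 at 1 h and −0.12 at 6 h. Kif20a, a kinesin of cytokinesis, had −0.49 at 6 h, Cenpe −0.54, Cenpf −0.51 and Plk1 −0.46. No member passed over all genes or adjusted over the list alone, and camera gave an adjusted p of 0.187 (0.92 with an estimated correlation); after quantile normalization it was called lower (adjusted p = 0.0199), the lowest of the 12 alternatives. Cenpe changed sign, to a mean log2 ratio of 0.18, when the median of its probe sets was used. The 20 measured genes of cytosolic ribosomal proteins were called higher by camera (adjusted p = 0.0176), with a median of the mean log2 ratios of 0.07. The call was lost with an estimated correlation of 0.118 (adjusted p = 0.788) and after quantile normalization (adjusted p = 0.514). That estimate was above the preset 0.01, so the preset may understate the correlation within this list. The range of its adjusted p over alternatives was 0.00193 to 0.788, with 0.0646 without the 1 h arrays and 0.203 without the 2 h arrays. No member passed. Rps27 had a mean of 0.70 ± 0.33, with ratios of 0.95, 1.41 and −0.27, vehicle signals under the filter value at 1 h and 2 h, and a range of the mean over alternatives of 0.34 to 1.18. The median of this list was 0.07 at 1 h, on the array with the bright 18S control, 0.12 at 2 h and 0.01 at 6 h.

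Circadian clock genes had a median log2 ratio of 0.10 at 1 h, at percentile 99.2 of random lists, and −0.19 at 2 h, at percentile 0.07. Bhlhe40, a clock-linked repressor gene, was 2.35-fold higher at 1 h on the array with the bright 18S control, and Dbp had −0.75 at 6 h. None of the 16 measured members passed either test (adjusted p = 0.502 by camera). The calcium and cyclic AMP signalling list had a median of 0.13 at 6 h, at percentile 99.7, with none of 25 members past either test (adjusted p = 0.473); Cacna1d, a calcium channel gene, had a mean of 0.41 ± 0.14, with a vehicle signal under the filter value at 6 h. No member passed either test, and camera made no call, for receptors and Smads (21 measured, adjusted p = 0.187, though 0.0167 with the median of probe sets), DNA replication (25, adjusted p = 0.473), the unfolded protein and integrated stress responses (22, adjusted p = 0.835), heat shock (10, adjusted p = 0.246), hypoxia and glycolysis (19, adjusted p = 0.502), secretory granules and exocytosis (22, adjusted p = 0.865), matrix and cytoskeleton (19, adjusted p = 0.865), interferon-stimulated genes (11, adjusted p = 0.835) and housekeeping genes (12, adjusted p = 0.95). The housekeeping list still lay at percentile 0.91 of random lists at 2 h, with a median of −0.027. Immediate early genes lay at 1.31 and 0.78 at 1 h and 2 h, so an extreme percentile alone does not set a list apart. Markers of other pituitary cell types had 5 measured members, none past either test (adjusted p = 0.337); Pomc, the corticotrope hormone gene, had 0.98 at 6 h. Of 6 measured markers of fibroblasts, endothelium and blood cells, Pecam1, an adhesion gene of endothelium, was higher adjusted over the list alone (0.72 ± 0.14), the macrophage genes Adgre1 and Csf1r were lower (−0.41 ± 0.08 and −0.37 ± 0.10), and 3 did not pass (adjusted p = 0.95 by camera).

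Genes outside the lists also kept 1 direction at all 3 times; those named here were chosen after their values were seen. The transposon-derived gene Zbed5 had log2 ratios of 1.79, 1.95 and 1.36 at 1, 2 and 6 h, the chemokine-scavenging receptor gene Ackr3 2.11, 2.36 and 0.90, Irak2, a kinase gene of interleukin-1 signalling, 1.06, 1.24 and 1.27, and Lzts1 1.06, 1.30 and 0.93. Fam43a had −0.56, −0.68 and −0.92, and Apbb3, an adaptor gene of the amyloid precursor protein, −0.78, −0.62 and −0.54; Myc, of the lists, had −1.05, −0.79 and −0.82. Olfr64 was lower at all 3 times too, with activin signals under the filter value at 2 h and 6 h. In total 279 genes were at least 1.2-fold apart the same way at all 3 times, 141 higher and 138 lower with activin, against 100, 108 and 105 when the arrays of 1, 2 or 6 h were exchanged. With each array centred on its median the split was 166 of 270 higher. At 1.5-fold, 21 genes were higher and 5 lower at all 3 times. The limma test of the time-averaged effect nevertheless passed 0 genes at a Benjamini-Hochberg threshold of 0.05 (smallest adjusted p 0.305), with 1195 genes at an unadjusted p under 0.05, 474 higher and 721 lower, where 570 would fall by chance. The surplus of lower genes may depend on scaling, but the split by direction was not counted under another scaling. In the deposited signals the median log2 ratio over all genes was −0.041, −0.026 and −0.025 at 1, 2 and 6 h, which favours lower calls. With a prior variance that follows expression and a robust fit, the same test passed 9 genes, all higher: Zbed5, Irak2, Lzts1, Cdkn2b, Irf2bp2, Rflnb, En2, Ets2 and Rtp4.

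The next question was how many genes differed at each time. At 1 h, 264 genes were at least 1.5-fold higher and 332 lower with activin; at 2 h, 305 and 319; at 6 h, 422 and 360. Vehicle arrays of different times, which share the treatment, gave 384 genes at least 1.5-fold apart between 1 and 2 h, 469 between 1 and 6 h and 394 between 2 and 6 h, so cultures without activin, harvested at different times, also differed in many genes. Activin arrays of different times gave 798, 1007 and 749 for the same pairs of times. Dim genes weigh heavily in the counts of activin against vehicle, since a filter at the 70th percentile left 213, 217 and 315 genes. The balance of higher and lower genes was not stable at 1 h or 2 h. At 1 h, 286 of 580 were higher with median centring, 313 of 630 with the median of probe sets and 61 of 113 at 2-fold, and in genes with several probe sets 585 probe sets were higher and 322 lower. The balance at 1 h moved toward lower genes with the filter at the 70th percentile (82 of 213 higher) and in genes also outside the range of the 3 vehicle arrays (201 of 508 higher). At 2 h, 151 of the 217 were higher, 321 of 553 after quantile normalization and 332 of 593 with median centring.

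**Figure D2:**
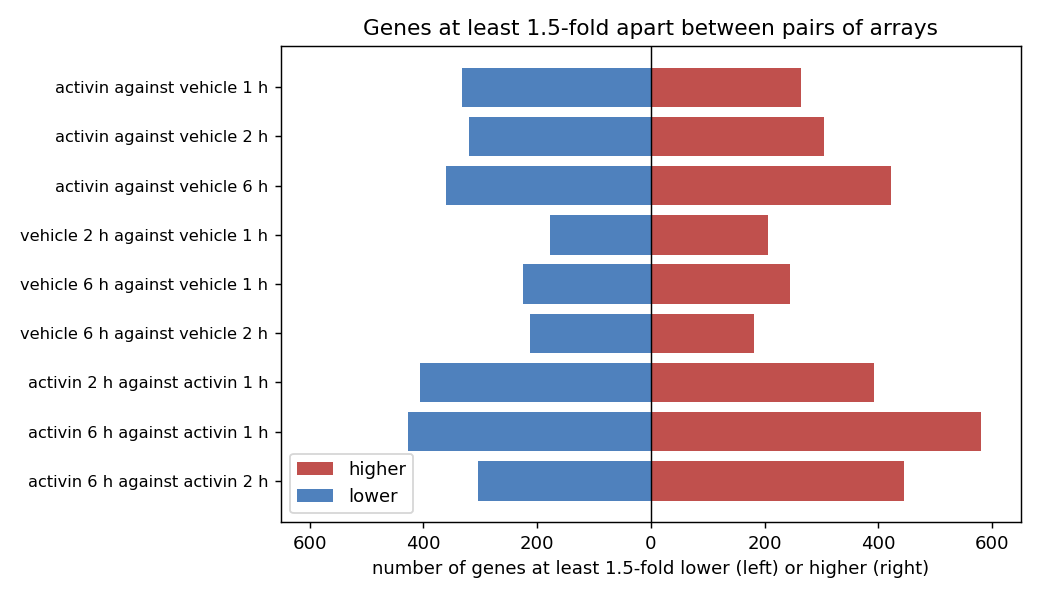
Bars count genes at least 1.5-fold higher (right, red) or lower (left, blue) between 2 arrays, for each of 9 pairs named on the vertical axis. The 3 pairs of activin and vehicle at 1 time gave 596, 624 and 782 genes, the 3 pairs of vehicle arrays gave 384, 469 and 394, and the 3 pairs of activin arrays gave 798, 1007 and 749.

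Named at each time were the genes with the highest and lowest ratios among those whose activin signal also lay outside all 3 vehicle arrays. Where the dimmer signal was under the filter value of 155.2, the fold is a lower bound against that value, a form chosen after the data were seen, and such folds are not ranked. At 1 h, Ackr3 was 4.32-fold, Zbed5 3.47-fold, Skil 3.17-fold and Irf2bp2 2.98-fold higher, Fbxw19 at least 3.21-fold and Sting1, an innate immune adaptor gene, at least 1.97-fold. Dclk2 was 3.17-fold lower, and Cfap61 at least 5.72-fold, Cpa3 at least 1.82-fold, Brsk1 at least 1.78-fold, Tspan5 at least 1.75-fold and Smim27 at least 1.32-fold lower. Ackr3, Sting1, Zbed5, Skil and Irf2bp2 were higher at all 3 times, while Fbxw19, Cpa3, Smim27 and Tspan5 were on the other side at 2 h and Cfap61 at 6 h. At 1 h these ratios come from the array with the bright 18S control. Of probe sets at least 1.5-fold higher at that time in genes with several probe sets, 21.4% were followed by the brightest other probe set of the gene, at least 1.2-fold higher, against 41.1% at 2 h and 49.2% at 6 h. Over all probe sets of such genes the shares were 12.1%, 10% and 13% at 1, 2 and 6 h.

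**Figure D3:**
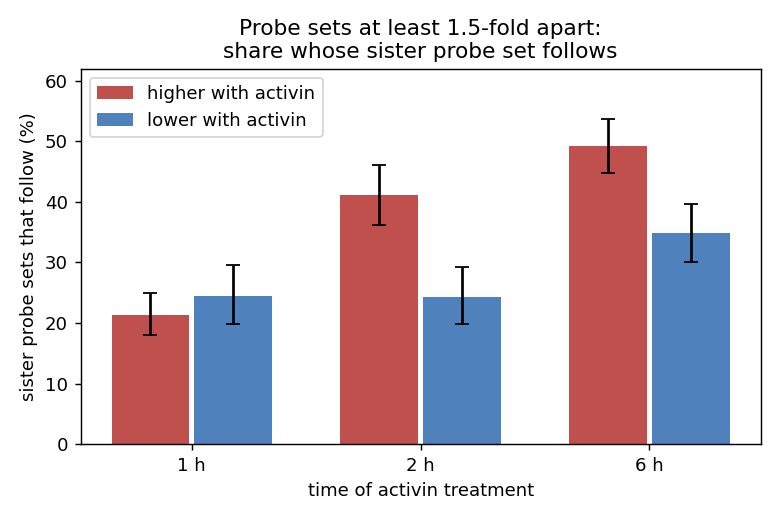
Bars give the percent of probe sets at least 1.5-fold higher (red) or lower (blue) with activin where the brightest other probe set of the gene was at least 1.2-fold apart the same way, with exact binomial 95% intervals, for each time. The intervals treat the probe sets as independent, which they are not. The share for higher probe sets was 21.4% at 1 h and 49.2% at 6 h, against 12.1% and 13% over all probe sets of such genes.

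At 2 h, Ell was 6.22-fold higher, Ackr3 5.12-fold and Lhfpl2 4.21-fold; Iffo2 was at least 2.38-fold, Zdbf2 at least 2.27-fold and Tnfsf4, a TNF family ligand gene, at least 1.99-fold higher. The fold of Ell rests on a low vehicle signal of 162 at 2 h, just above the filter value, where vehicle read 439 at 1 h and 524.2 at 6 h. Lhfpl2 was also 3.29-fold higher at 6 h. Lower at 2 h were Otp (at least 4.89-fold), Arhgap27 (at least 2.93-fold), the olfactory receptor gene Olfr64 (at least 2.57-fold), Azgp1 (at least 2.30-fold), Cacna1b (at least 1.84-fold) and Rbms3 (at least 1.79-fold). The fold of Otp rests in part on a high vehicle signal of 758.3 at 2 h, against 276.6 at 1 h and 382.8 at 6 h. At 6 h, Hsd17b1, an enzyme gene of estradiol synthesis, was 4.47-fold and Chp2 4.39-fold higher. The calcium pump gene Atp2c2 was at least 3.32-fold higher at that time, Tuba3b at least 3.20-fold, the calcium channel gene Cacna1a at least 2.88-fold and Pear1 at least 2.65-fold. Chp2 was higher at all 3 times, with a log2 ratio of 0.88 at 1 h. Lower at 6 h were Olfr64 (at least 3.94-fold), Ccl8 (at least 2.18-fold), Ahnak (at least 2.17-fold), Lmo3 (at least 1.83-fold), Fam160a1 (at least 1.72-fold) and Clip4 (at least 1.71-fold).

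Ratios at different times share no array, and they were weakly related across genes. Pearson's r was 0.14 between 1 h and 2 h, 0.15 between 1 h and 6 h and 0.21 between 2 h and 6 h, with Spearman's rho of 0.14, 0.15 and 0.18. Among the brightest 3803 genes r was 0.33, 0.21 and 0.40. Genes at least 1.5-fold higher at both 2 h and 6 h numbered 102, where independent lists of those sizes would share 11.3; for 1 h and 2 h the overlap was 55 against 7.06. Lower genes shared 50 against 10.1 and 27 against 9.28. The counts for independent lists give every gene the same chance to pass 1.5-fold, while dim genes pass more often, so they are too low as a reference. Genes are not independent replicates, and no p-value was taken from these relations.

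Time was the last comparison, over both treatments. Time in serum-free medium, time since treatment and any difference in handling between the harvests cannot be told apart, since each time has 1 pair of arrays. The SE values hold no variation between repeated harvests of the same time. Expression of the collagen gene Col2a1 was 1.41 ± 0.12 higher on the log2 scale at 6 h than at 1 h, Rbm12b1 1.51 ± 0.12, Ier3 0.89 ± 0.10 and Ankrd37, a hypoxia-linked gene, 0.92 ± 0.12. Rasl10b had a difference of −1.58 ± 0.16, the transcriptional co-activator gene Cited4 −1.23 ± 0.14, and Nagpa, an enzyme gene of lysosomal targeting, −0.89 ± 0.10. These genes were chosen after their values were seen, by their unadjusted p, and Col2a1, Rbm12b1 and Ier3 had signals under the filter value on 1 or both arrays of 1 h. None passed the limma test adjusted over all genes (smallest adjusted p 0.465, 0 genes), with 1109 genes at an unadjusted p under 0.05, of which 582 were higher at 6 h. For 2 h against 1 h, 0 genes passed and 773 were at an unadjusted p under 0.05.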

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

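The tests on the 18S signal were chosen after the result was seen, and the test on hybridisation controls took the place of an earlier test, given below, that had only restated the pattern; the test on sister probe sets was written before its result was seen.

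Control probe sets for 18S ribosomal RNA, which no comparison uses, were brightest on the activin 1 h array. The 5′ probe set read 12202 there against 610 on the vehicle 1 h array, 20-fold apart, and the probe sets for the middle and 3′ regions were 3.89-fold and 3.01-fold apart. Degraded RNA on that array is argued against, since the 3′ over 5′ ratio of Actb was 1.176, below the highest of the other arrays (1.274), and that of Gapdh was 0.793 against at most 0.836. More ribosomal RNA in the labelled target stays open. The earlier test asked whether all 3 probe sets were brightest on that array, and they were, with the smallest excess over the next array at 2.39-fold, but this is the pattern itself and decides nothing. In its place, hybridisation controls were 1.12-fold brighter there than on the next array, a smaller excess than the 1.2-fold set for a call. A rise of 18S signal with activin stays open too, as the median of the 6 activin over vehicle ratios at 2 h and 6 h was 1.13, with 1 of them at 1.82, and no second culture at 1 h was measured.

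Probe sets at least 1.5-fold brighter with activin at 1 h were followed by their sister probe sets less often than at the later times. In genes with several probe sets past the filter there were 585 such probe sets at 1 h, and in 21.4% (exact binomial 95% interval 18.1% to 24.9%) the brightest other probe set of the gene was at least 1.2-fold brighter, against 41.1% (36.2% to 46.1%) of 399 at 2 h and 49.2% (44.7% to 53.7%) of 492 at 6 h. Over all probe sets of such genes the shares were 12.1%, 10% and 13%. The intervals treat probe sets as independent, though some share a gene and all of a time share 1 pair of arrays. They therefore understate the uncertainty. For probe sets at least 1.5-fold lower the shares were 24.5%, 24.3% and 34.8%, so at 1 h and 2 h they lay close together. A candidate explanation is a fault of the activin 1 h array that moves individual probe sets upward, since a lower share at 1 h was predicted before the test and 21.4% lay below the intervals of the later times. The test cannot single out such a fault, since fewer genes truly changed at 1 h would lower the share as well. An early change of transcript ends or of unspliced RNA, which would also part the probe sets of a gene, was not tested and stays open.

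The next 6 results are values with no test of the difference between times, in genes at least 1.5-fold higher at 1 time and at least 1.5-fold lower at another. The highest and lowest log2 ratios of Cfap61 were 5.057 apart, those of Cpa3 3.413, Iffo2 3.238, Fbxw19 3.001, Zdbf2 2.958 and Clip4 2.881. In each of these genes at least 1 of the signals was under the filter value of 155.2, so the sizes are not well measured.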

How the results depend on the processing

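The settings with a signal difference of 100, without the activin 1 h array, and the correlation without 1 h were chosen after seeing the data. Without a filter, 3292, 3524 and 3709 genes were at least 1.5-fold apart at 1, 2 and 6 h, 899 were 1.2-fold apart the same way at all times (780 at most with a time exchanged), the mean correlation between times fell from 0.166 to 0.021 and 0 lists were called, so results for dim probe sets are limited by signal over background. With the filter at the 70th percentile, these were 213, 217, 315, 153 (29 at most with a time exchanged), 0.28 and 2, and the time-averaged test passed 3 genes (Zbed5, Irak2 and Lzts1). It passed 9 with limma-trend and a robust prior, and 0 under the other settings, with 841 to 1233 genes at an unadjusted p under 0.05. At 2-fold, 113, 128 and 168 genes were counted; at 1.5-fold at all times, 26; and with a signal difference of at least 100, 163. Leaving out each time gave 737 to 908 genes over the remaining 2 times (409 to 450 with a time exchanged), since fewer arrays must meet the threshold, and 0 to 4 called lists: 0 without 1 h, 0 without 2 h and 4 without 6 h. The correlation without 1 h was 0.209. Camera with an estimated correlation and the directional test of fry called 0 lists. The mixed test of fry, which counts changes in either direction, passed 12 of 25. Among them were BMP-responsive genes (adjusted p = 0.000528) and the activin and Notch lists (adjusted p = 0.00412 each). It also passed markers of fibroblasts, endothelium and blood cells (adjusted p = 0.0198) and secretory granule genes (adjusted p = 0.0291). Passing the mixed test is therefore not particular to activin signalling. The correlations estimated for the activin, BMP and gonadotrope lists were below the preset value. A larger estimate was therefore not what lost their calls in camera with an estimated correlation. Each estimate rests on 2 residual degrees of freedom and cannot exclude correlation between genes. Of 74 counts under alternatives, 50 stayed within 1.5 times of the reported count. The 50 include tests that passed 0 genes both as reported and under the alternative, among them all 9 settings of 6 h against 1 h. Of 300 list tests under alternatives, 25 lost and 2 gained a call, and 273 kept their side. Of 224 log2 ratios of named genes at single times, 53 moved by more than the spread between vehicle arrays and none changed sign. These genes were chosen for extreme ratios outside the range of all 3 vehicle arrays, so a change of sign was unlikely. Against the mean of those arrays it was impossible. The cause was not tested where none is given. The test of 6 h against 1 h passed 0 genes under all 9 settings tried.

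Of 1315 mean log2 ratios of named genes under alternatives, 11 changed sign, none past the test, and 9 passed it, all 3 of the 70th percentile filter and 6 of the limma-trend genes. The changes of sign were Cenpe 0.177, Rora −0.125 and Pgk1 −0.007 with the median of probe sets, and, when a time was left out, ranges of −0.129 to 0.548 for Id3, −0.054 to 0.86 for Ddit3, −0.003 to 0.123 for Pgk1, −0.127 to 0.287 for Egr1 (−0.038 without 2 h), −0.317 to 0.014 for Smad3, −0.028 to 0.164 for Tshb and −0.044 to 0.319 for Cdkn2a. The vehicle signal of Ddit3 at 1 h was 73.4, under the filter value, so the upper end of its range is not well measured.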

Other observations

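Of the tests below, those of other assignments of the arrays within times were chosen after the result was seen, and the others before.

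The authors' deposited table of genes past 1.2-fold at all 3 times names further genes, of which 38 of 46 entries were matched to a probe set by accession. The deposited signals gave Socs2, a feedback inhibitor of cytokine signalling, log2 ratios of 1.48, 2.16 and 2.28 at 1, 2 and 6 h, where the authors' deposited table lists folds of 1.28, 1.65 and 1.84; the brightest Socs2 probe set did not share this, at −0.81, −0.12 and 0.37. Slc40a1, the iron exporter gene, had 0.62, 1.08 and 1.73 (folds of 1.49, 1.96 and 2.62 in the authors' deposited table), and the matched probe set of Rassf4 had 1.27, 1.37 and 1.58, against 0.07, 0.55 and 0.55 for its brightest probe set. These genes were chosen after their values were seen. The transcription factor genes En2 and Ets2 had ratios between 0.49 and 0.87 at all 3 times, while Sox11 had 0.82, 0.83 and 0.58 in the matched probe set and 0.26, 0.16 and −0.15 in its brightest. Galnt10, a glycosyltransferase gene, had −0.18, 0.91 and 1.11, and the matched probe set of Rorb had 1.97, 0.23 and −0.14; its brightest probe set had 0.61, −0.16 and −0.48. Galnt10, Rorb and Ppp1r12a are the 3 of the 46 entries in the authors' deposited table that do not have 1 sign at all times.

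Signs in the authors' deposited table were shared by the ratios of the deposited signals in 35, 38 and 36 of the 38 matched entries at 1, 2 and 6 h, with Pearson's r across entries of 0.78, 0.83 and 0.80. Sizes differed: the median absolute log2 ratio of the deposited signals was 1.02, 1.33 and 1.3 times that of the authors' deposited table at the 3 times, for a reason not known here. Its headers state 130 genes at all 3 times, 96 higher and 34 lower, and 347, 112 and 205 genes past 1.5-fold at 1, 2 and 6 h. With the stated fold and a signal difference over 100, the deposited signals gave 338 probe sets at all 3 times (215 higher and 123 lower) and 1738, 1509 and 1926 at the single times. Those counts take no detection calls into account, which were not used here.

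The 279 genes at least 1.2-fold apart the same way at all 3 times were weighed against technical explanations. Noise of dim probe sets is argued against as the whole account, since among the brightest 3803 genes the real count was 42 against at most 4 with a time exchanged, 10.5 times as many, though among the dimmest 3803 genes it was 147 against 91. A scaling or brightness difference is argued against by quantile normalization, which left 262 genes against 106, a factor of 2.47. Noise of individual probe sets is argued against too: of 163 sister probe sets of these genes, 78.5% (exact binomial 95% interval 71.4% to 84.6%) had a mean ratio of the same sign, against 59.5% for all genes with sisters. A shared response to activin may account for part of the 279, as a hypothesis, while a difference between how the activin and vehicle cultures were handled cannot be separated from treatment in this design, and with 4 assignments (1 of them, the real one, reached 279; the highest other gave 108) chance cannot be given a share under 0.05.

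The 6 arrays allow 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 1195 genes at an unadjusted p under 0.05 and the highest other 828, and 1 of the 10, the real one, reached that count. The model pairs the arrays by time, and 4 of the 10 splits keep 1 array of each time on each side, the real one and 3 others, of which the highest gave 434. The other 6 put both arrays of a time on 1 side and came in 3 couples of equal counts, so the 10 are not distinct and do not all respect the pairing. For genes past the adjusted threshold all 10 splits gave 0. For lists called by camera, 1 of the 10 splits reached the 4 of the real one, and the highest other gave 1.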
